A study of Mus musculus with 6 samples.

How the data were processed

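Gene expression was measured with Illumina bead arrays in cultured muscle satellite cells, the stem cells of skeletal muscle, from mice that carry a Bmi1 transgene behind a floxed stop cassette. Bmi1 is a Polycomb group protein. The 6 cultures had differentiated for 2 days. Of these, 3 had been infected with an adenovirus that delivers Cre recombinase, the enzyme that removes the stop cassette, and 3 with an adenovirus that delivers GFP, which leaves the cassette in place. The groups are called Cre and GFP below, and groups and replicate numbers 1 to 3 were taken from the sample titles. The labels call the replicates biological but do not say whether each came from its own animal, so the p-values measure only the spread between these 6 samples.

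The deposited non-normalised table gives an average bead signal per probe, an intensity on a linear scale that had not been background-subtracted, as its lowest value on any array was 28.4. It also gives a deposited detection score per probe and array. Per the file headers this column is a detection p-value, but its values rose with the signal (rank correlation of at least 0.988 on each array), so the score was read as 1 minus the detection p. The authors also deposited log2 values of the same 45281 probes, which have almost the same distribution on each array (medians from 4.09 to 4.10, maximum 14.8). Each of these log2 columns ranked the probes as the signal of its own array did (rank correlation 1.00), and correlated at 0.999 or more with the values computed here. That scale and direction fit a background-corrected, quantile-type normalisation on the log2 scale, but the steps are not given in the sources used here. The submitters' processing notes name lumi, without a version. The genome build is not given in the sources used here and no coordinates were used.

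The probes carry Illumina identifiers only. None of the identifiers occurs in the gene table used here, and 0 probes could be given a gene name. Probes therefore took the place of genes, as the design written before the data were examined provided for. The levels of Bmi1 and of Mt1, which the series title names, the 18 gene lists and 6 cell type marker lists fixed in advance, and the alternatives that average the probes of a gene were not analysed here. The alternative that tests all kept probes became the main setting.

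Signals were background-corrected and normalised with neqc in limma 3.58.1 under R 4.3.3, which infers the background from the detection p, adds an offset of 16 and quantile-normalises the log2 values. A probe was kept if its detection p was under 0.01 on at least 3 of the 6 arrays, which left 13110 probes, 29.0% of the table. Of these, 8636 were detected on all 6 arrays. The Cre and GFP groups were compared with limma's lmFit and eBayes (two-sided), and a probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all probes kept. The fit had no covariate, as fixed before the data were examined, and a second fit had the replicate number as a block. Values are normalised log2 signals, and differences are Cre minus GFP. Intervals on differences are 95% intervals of the limma fit.

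Whether the replicate numbers pair the samples was decided from the arrays' deviations and not from the calls. Over the 13110 probes, the deviations from the group means correlated between the arrays of one number at 0.54 for replicate 1, 0.66 for replicate 2 and 0.51 for replicate 3. These all lie above the limit of 0.1 set for treating the numbers as pairs, so the paired fit is given beside each result. The pairing comes from the data and the shared numbers, not from a statement in the labels. By the array codes, the 6 arrays filled the 6 positions of 1 slide, with the 2 arrays of a number side by side, so slide was no batch, but position and replicate number go together.

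The rule for named probes, fixed before the data were examined, took the 12 largest called changes in each direction and, where too few passed, filled to 5 per direction with the smallest unadjusted p among the fits without the block. As no gene names are available, at most 2 identifiers per direction are printed. These are the first 2 higher probes of the rule, the first lower probe, and the 1 probe called with the block, which was chosen after its values were seen. Arrays give no read depth; their number limits the precision.

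The fits were tested on simulated data made from the 13110 probes' own means, replicate effects and residual spread, with 200 probes changed in each of 5 draws. The noise was independent between probes, and its spread came from variances that limma had drawn towards a common value. The shares called can therefore be higher than in the real data. The fit without the block called 0 of the probes changed by 1 log2 unit and 1.8% of those changed by 2 log2 units. The paired fit called 50.4% and 100.0% of them, with a mean of 9.2 false calls per draw, and a mean of 0.2 calls where nothing had been changed.

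Alternatives were no background correction, normexp with an offset of 50, centring each array on its median, the authors' deposited log2 values, 3 other filters on dim probes, an intensity trend with robust hyperparameters, array weights, a log2 difference of at least 0.58, the replicate block, and leaving out each array in turn. The same settings combined with the block, and fits without both arrays of a number, were added after seeing the data. No group had more than 3 samples, so no test for outlying arrays was made. Figures were drawn with matplotlib 3.10.9.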

Results

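The data set comprised 6 arrays of 45281 probes, 3 from satellite cell cultures infected with adenovirus carrying Cre and 3 from cultures infected with adenovirus carrying GFP. The mean signal per array was 178 ± 80.4 (SD, n = 3) in the GFP group and 140 ± 50.4 (SD, n = 3) in the Cre group. It ranged from 102 on the array of Cre replicate 2 to 263 on that of GFP replicate 1. The number of probes detected followed the signal, from 10003 for Cre replicate 2 to 15859 for GFP replicate 1. The group means were 13364 ± 2320 (SD, n = 3) for GFP and 12038 ± 2318 (SD, n = 3) for Cre. Neither the log2 mean signal nor the number of probes detected differed between the groups beyond the spread of the arrays (exact permutation test, two-sided, p = 0.6 for each; the smallest p that 3 against 3 allows is 0.1).

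The first question was how far the cultures differed from one another irrespective of virus. The arrays grouped by replicate number rather than by virus, and each array correlated best with the other array of its own number. The array most similar to GFP replicate 1 was Cre replicate 1 (r = 0.977 over the 13110 probes kept), and GFP replicate 3 and Cre replicate 3 correlated at 0.962. The 2 arrays of replicate 2 correlated at 0.927 with each other and stood apart from the other 4 on the first principal component, which held 51.4% of the variation. The highest correlation between 2 arrays of one group was 0.960, below that of GFP replicate 1 with Cre replicate 1, so no 2 replicates of a group were treated as one library. Of the summed squared deviations over all probes, 66.7% lay between replicate numbers, 15.3% between the viruses and 18.1% in neither, where an even share per degree of freedom would give 40%, 20% and 40%. In the paired limma fit, 2499 probes (19.1%) differed between replicate numbers at an adjusted p under 0.05. On the first component, Cre replicate 2 scored 73.1 and GFP replicate 2 scored 38.5. Array weights, which count more variable arrays for less, were 0.30 for Cre replicate 2 and 0.70 to 2.22 for the others (without the block). How far the share between replicate numbers rests on the array of Cre replicate 2 was not tested.

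**Figure D1:**
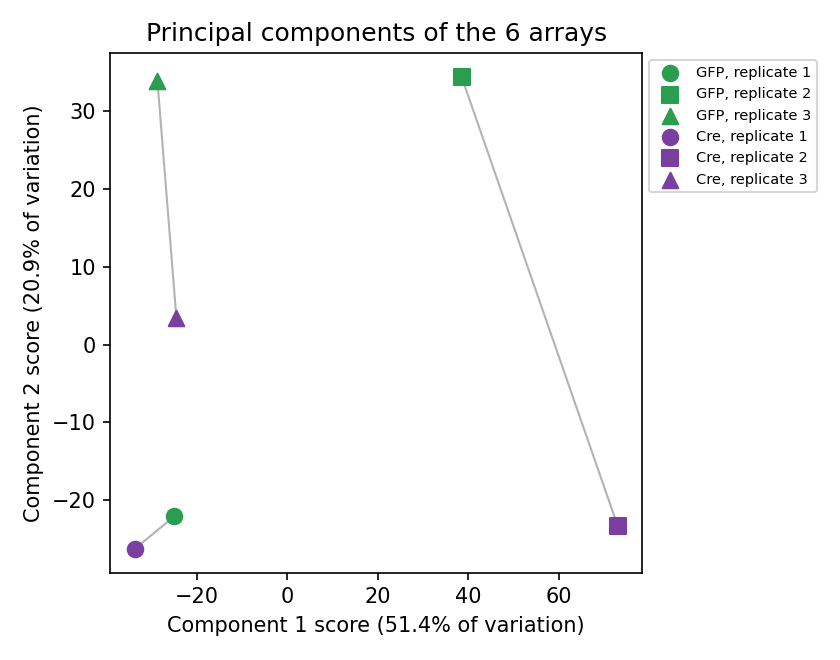
Scores of the 6 arrays on the first and second principal components of the normalised log2 signals of 13110 probes; each axis gives its share of the variation, and a grey line joins the arrays of one replicate number. Component 1, with 51.4% of the variation, separates both replicate 2 arrays from the other 4, and the GFP and Cre arrays do not form separate groups.

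The comparison the study was designed for asks which transcripts change when Cre switches on the Bmi1 transgene in differentiating satellite cells. Without the replicate block, limma called 0 of 13110 probes at an adjusted p under 0.05 (smallest adjusted p = 1.00), with 380 probes at an unadjusted p under 0.05 where 656 would be found by chance. With the replicate number as a block, 1 probe was called, and it was lower in Cre. Then 1428 probes (10.9%) had an unadjusted p under 0.05, 571 of them higher and 857 lower in Cre. These counts depended on the scaling, as centring each array on its median left 50 probes at an unadjusted p under 0.05 in the paired fit, 1 higher and 49 lower. The split also depended on the filter, with 548 higher and 502 lower among the probes detected on all 6 arrays, and 1408 higher and 1338 lower without a filter. With both arrays of one number left out, the paired fit called 96 probes without replicate 1, 42 without replicate 2 and 44 without replicate 3, each from 1 residual degree of freedom. Each of these fits called 0 probes with the labels of 1 pair swapped, which puts a difference shared by the pairs into the residual. In simulated data of 2 pairs where nothing had been changed, the paired fit called a mean of 0.6 probes per draw (highest 3). That simulation covered only the fit without replicate 1, which called 96 probes. Its noise had a spread already drawn towards a common value, and was simpler than that of the arrays. The simulation therefore cannot decide whether 1 residual degree of freedom was the source of the 42 to 96 calls. Other causes were not tested. On all arrays, the paired fit called 9 probes with an intensity trend and robust hyperparameters, and 6 with array weights. Most differences were small, as 98.4% of the probes differed by less than 1 log2 unit between the group means. The other probes were 40 with a mean at least 1 log2 unit higher in Cre and 175 with a mean at least 1 log2 unit lower. The median half-width of the 95% interval on a difference was 0.82 log2 units (1.77-fold) without the block and 0.57 log2 units (1.49-fold) with it. These intervals are not adjusted for the number of probes. In simulated data of this size and spread, the fit without the block called 1.8% of probes changed by 2 log2 units, and the paired fit called 50.4% of those changed by 1 log2 unit. These shares can be too high, since the simulated noise was simpler than that of the arrays. In the real data, the paired fit did not call a probe 2.53 log2 units higher in Cre (adjusted p = 0.0755 in limma). That probe was called with the block and array weights (adjusted p = 0.0441 in limma). Each paired fit without both arrays of a number called it too.

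**Figure D2:**
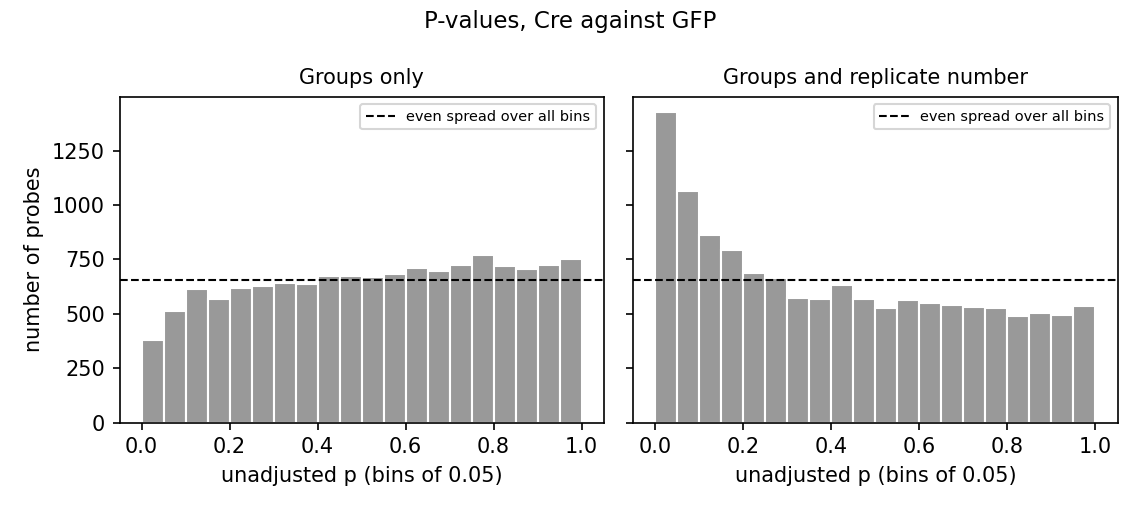
Number of probes (vertical axis) in bins of 0.05 of the unadjusted limma p (horizontal axis) for Cre against GFP, from the fit on groups alone (left) and the fit with the replicate number as a block (right); the dashed line is an even spread. The lowest bin holds 380 probes on the left and 1428 on the right, where an even spread gives 656.

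The probe called in the paired fit was ILMN_2476405, whose gene is not named in the files used here. Its normalised log2 signal was 10.18 ± 2.70 (SD, n = 3) in GFP and 5.70 ± 2.45 (SD, n = 3) in Cre. It fell by 4.47 log2 units (SE 0.54 and adjusted p = 0.0143 with limma and the replicate block), and it was lower in Cre in 3 of 3 pairs. That SE rests on a variance drawn towards a common value of all probes, with 11.5 prior against 2 residual degrees of freedom. The scatter of this probe's own 3 pair differences would give a larger SE. The probe was detected on all 3 GFP arrays and on 1 of 3 Cre arrays. The pair in which both arrays detected it, replicate 3, had a difference of -3.71, while the differences of replicates 1 (-2.83) and 2 (-6.88) were taken against a Cre signal not above background. The mean difference depended on the treatment of the background, and was -3.63 without background correction and -3.39 with a normexp offset of 50. Its level also differed widely between cultures that had received the same virus, from 7.12 in GFP replicate 1 to 12.24 in GFP replicate 3, and the fit without the block did not call it (adjusted p = 1.00). With the block, the call was also lost with the authors' deposited log2 values (adjusted p = 0.0890), without background correction (0.0561), with a normexp offset of 50 (0.126), with an intensity trend and robust hyperparameters together (0.369) and without the filter on dim probes (0.713).

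Among the probes with the smallest unadjusted p in the fit without the block, none passed the threshold in that fit or with the block alone, and their values are given for that reason as measurements only. ILMN_2629591 had a log2 signal of 6.47 ± 0.26 in GFP and 4.73 ± 0.34 in Cre (SD, n = 3 each), a difference of -1.74 (SE 0.32) with an adjusted p of 1.00 in limma, or 0.0844 with the block. It was lower in Cre in 3 of 3 pairs. All 3 GFP arrays and 2 of 3 Cre arrays detected it. With the block, the difference of this dim probe was -1.01 without background correction, and it was called with an intensity trend and robust hyperparameters (adjusted p = 0.0485) and with array weights (adjusted p = 0.0457). ILMN_2596522 was among the brightest probes, at rank 26 of 13110 by mean signal, with 13.14 ± 0.30 in GFP and 14.37 ± 0.28 in Cre (SD, n = 3 each). The difference of 1.23 (SE 0.32; 2.35-fold) had an adjusted p of 1.00 in limma, or 0.153 with the block, and the probe was higher in Cre in 3 of 3 pairs, by 0.85 to 1.47. It was called with the block, an intensity trend and robust hyperparameters together (adjusted p = 0.0485). ILMN_2628757 was measured at 6.63 ± 0.27 in GFP and 7.95 ± 0.38 in Cre (SD, n = 3 each). Its difference was 1.32 (SE 0.33), with an adjusted p of 1.00 in limma, or 0.158 with the block, and a higher value in Cre in 3 of 3 pairs. The paired limma fits without both arrays of a number, each with 1 residual degree of freedom, also called these probes in part. ILMN_2629591 was called in each of them, ILMN_2596522 only without replicate 2 (adjusted p = 0.00872) and ILMN_2628757 only without replicate 1 (adjusted p = 0.0403).

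**Figure D3:**
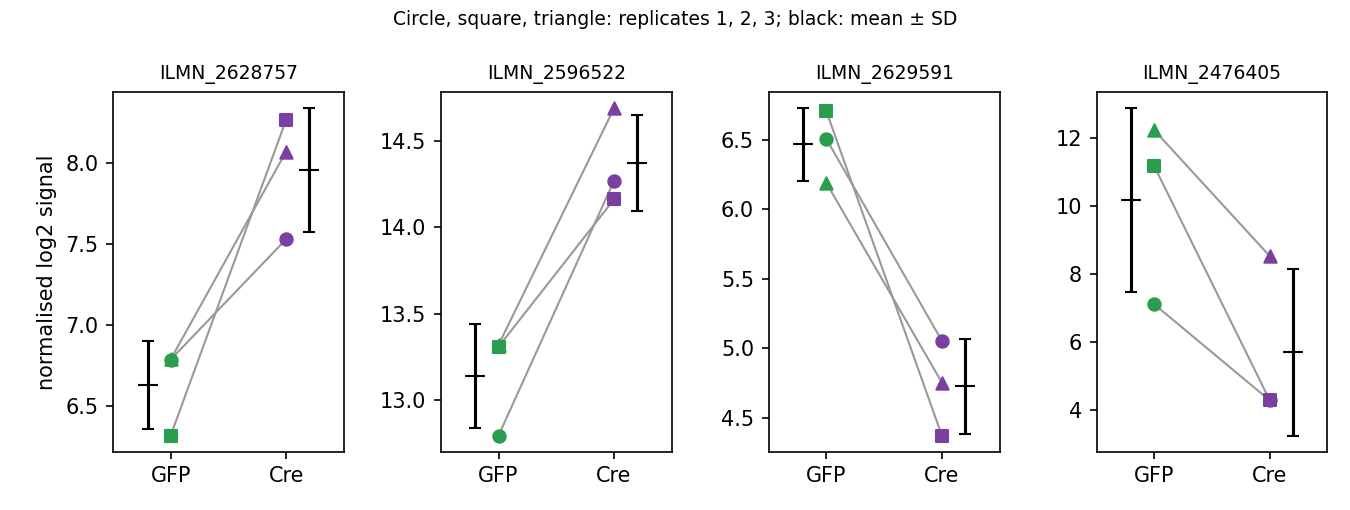
Normalised log2 signal (vertical axes, a separate range for each probe) of 4 probes in the GFP and Cre arrays; symbols are single arrays, grey lines join the arrays of one replicate number, and black marks are the group mean ± SD (n = 3). Each probe moved the same way in 3 of 3 pairs; ILMN_2476405 spans 7.12 to 12.24 among the GFP arrays, while ILMN_2629591 spans 6.19 to 6.70.

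The 3 pairs were also compared with one another. Across all kept probes, the Cre minus GFP differences of replicates 2 and 3 correlated at r = 0.31 (Spearman's rho 0.27), those of replicates 1 and 2 at 0.19 (rho 0.19) and those of replicates 1 and 3 at 0.05 (rho 0.04). These correlations are across probes, which are not independent replicates. In all 3 pairs, 2183 probes were higher in Cre and 2152 were lower, together 33.1% of the probes, where chance gives 25%. Without regard to pairs, all Cre values lay above or all lay below the GFP values for 8.71% of the probes, where chance gives 10%. A difference of over 1 log2 unit in every pair was seen for 9 probes lower in Cre and 1 higher in Cre. The differences were widest in replicate 2 (SD over probes 0.74 log2 units) and narrowest in replicate 1 (SD 0.41). Replicate 2 held the dimmest array, Cre replicate 2 (mean signal 102.2). GFP replicate 3 was almost as dim (102.6), and the SD of replicate 3 was 0.52.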

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

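All combinations with the replicate block other than the block alone, and all fits that left out both arrays of a number, were chosen after seeing the data. Without the block, limma called 0 probes under each of 19 alternatives, among them the authors' deposited log2 values (368 probes at an unadjusted p under 0.05), no filter (1833 of 45281 probes) and leaving out each array in turn (0 to 0 calls, with 198 probes at an unadjusted p under 0.05 without GFP replicate 2 to 512 without GFP replicate 1). The replicate block raised the count from 0 to 1 (0 higher, 1 lower in Cre), and so did the block with a log2 difference of at least 0.58, with each array centred on its median, or with detection p under 0.05 on at least 3 arrays. The block with an intensity trend and robust hyperparameters called 9 probes (1 higher, 8 lower), and the block with array weights called 6 (1 higher, 5 lower), of which 4 were shared. The probe called with the block alone was among the 6 but not among the 9. Of the 11 settings with the block on all arrays, 5 called 0 probes: no background correction, normexp with offset 50, the authors' values, no filter, and detection on all 6 arrays, which does not test the called probe. With the block and both arrays of one number left out, the count was 96 without replicate 1 (13 higher, 83 lower), 42 without replicate 2 (12 higher, 30 lower) and 44 without replicate 3 (8 higher, 36 lower). These fits have 1 residual degree of freedom, and those without replicate 2 or 3 gave every probe the same variance. Centring on the median moved the median of all differences to -0.32 log2 units, so that 57 of 57 probes at an unadjusted p under 0.05 were lower in Cre without the block, against 70.8% of 380 after quantile normalisation. For the 12 probes followed singly, none of 356 values under alternatives changed direction. These probes were picked by small p in the same arrays, so a kept direction is no separate support. Of the values, 34 passed the threshold where the main fit did not, all of them in fits with the block. Another 16 could not be given because the probe was not detected on all 6 arrays. The adjusted p of ILMN_2476405 with the block on all arrays ranged from 0.000738 to 0.713. The lowest value came from centring each array on its median, where the paired fit also gave every probe the same variance. Dim signal limits the data, since Cre replicate 2 detected only 22.1% of its probes.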

Other observations

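The tests of array brightness, of slide position and of the splits of the paired fit were chosen after the results were seen; the limits for the tests of the excess of lower probes were set before theirs, and how the intervals were held to them was settled after. In the paired fit, the probe with the second smallest p ran opposite to ILMN_2476405 in each pair. It was 1.81, 3.99 and 1.79 log2 units higher in Cre in replicates 1, 2 and 3 (mean difference 2.53; adjusted p = 0.0755 in limma with the block), and it too differed widely between cultures with the same virus, from 6.93 to 10.87 within the GFP group. With array weights besides the block it was called (adjusted p = 0.0441 in limma). It was singled out after its values were seen.

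Arrays with one replicate number deviated together, and replicate number held 66.7% of the variation. Array brightness as its whole cause is argued against by the brightness itself. The Cre and GFP arrays of one number differed by a mean of 0.93 in log2 mean signal, more than the mean of 0.45 over the 6 combinations of a Cre and a GFP array of different numbers. The smallest gap within a number, 0.72, was larger than that of 5 of these 6 combinations. Position on the slide stays open: the deviations of neighbouring Cre and GFP arrays of different numbers correlated at a mean of -0.35, within the range of the other 4 combinations of a Cre and a GFP array of different numbers (-0.60 to 0.15), with only 2 such neighbours. Deviations from a group mean cancel within the group, so positive correlations within numbers force negative ones on average between them. The negative sign therefore tells nothing about position. A shared animal, preparation or day of culture was not tested, since the labels do not give one.

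Other splits of the 6 arrays are too few for a share under 0.05. The real split called 0 probes without the block, and so did each of the other splits, 10 of 10 in all (highest other 0). The 3 splits with the most probes at an unadjusted p under 0.05 (1524, 1754 and 1819, against 380 for the real split) each kept both replicate 2 arrays on one side, which points to a structure of the samples. Among the 4 splits that part all 3 pairs, the paired fit called 1 probe for the real split and 0 for each other one (1 of 4 as large). Their counts at an unadjusted p under 0.05 were 1428 for the real split and 161, 438 and 723 for the others.

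The excess of probes lower in Cre (857 of 1428, 60.0%, at an unadjusted p under 0.05 in the paired fit) was not seen among probes detected on all 6 arrays (502 of 1050, 47.8%) or without a filter (1338 of 2746, 48.7%). With each array centred on its median it was 49 of 50, in place of 1428 probes, and the median of all differences moved to -0.32, so both the count and the split depend on the normalisation. Dimmer Cre arrays were considered, since the Cre array was the dimmer one in replicates 1 and 2 and the brighter one in replicate 3. In replicate 3, 56.6% of the 785 probes over 1 log2 unit apart were lower in Cre (Wilson 95% interval 53.1 to 60.0, counting probes as independent), where that explanation required at most 45%. Replicate 1, with the largest dimming of the Cre array, had 53.9% lower, and replicate 2, whose Cre array was also the dimmer one, had 61.6%. The paired fit without replicate 2 had 810 probes at an unadjusted p under 0.05, and 54.4% of them were lower in Cre. That share was 60.0% without replicate 1 and 66.7% without replicate 3. The 56.6% within replicate 3 argues against dimmer arrays as the whole cause. A part in replicate 2, without which the excess was smaller, stays open. Probes near the background were considered by splitting at the median mean signal. The brighter probes gave 57.2% lower (53.5 to 60.9), where at most 50% was required, and the dimmer ones 62.6% (59.0 to 66.0). Each set mixes probes detected on all 6 arrays with others, so this split cannot decide whether the background is the whole cause. Among the dimmer probes, 34.2% of the 184 detected on all 6 arrays were lower and 71.8% of the 561 others. Among the brighter probes, these shares were 55.4% of 650 and 93.9% of 33. Much of the excess therefore lay in probes near the detection limit. A filter on all 6 arrays itself removes probes that fell below detection in either group. The main filter, on at least 3 arrays, also keeps probes detected in a single group. This filter and the normalisation stay open as technical sources. Cre itself, GFP, which only the control virus delivers, the loss of the stop cassette and Bmi1 differ together between the groups. Their contributions cannot be separated with these arrays.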
